A study of Homo sapiens and Mus musculus with 40 samples.

How the data were processed

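The series combined snoKARR-seq, a proximity ligation assay for the partners of small nucleolar RNAs (snoRNAs), with small RNA-seq. Per the labels' protocols, RNA was labelled with N3-kethoxal, the cells were fixed with formaldehyde, RNAs close to each other were linked through a dendrimer and ligated, and cDNA of chosen snoRNAs was enriched with antisense oligonucleotides, while 10% of the cDNA was kept as input. The 40 samples were 34 snoKARR-seq libraries and 6 small RNA-seq libraries, all in duplicates. The snoKARR-seq libraries came from the human lines HepG2 (liver cancer), HEK293T (embryonic kidney), PC3 (prostate cancer), A549 (lung cancer) and MDA-MB-231 (breast cancer) and from mouse brain; PC3, A549 and MDA-MB-231 also had small RNA-seq. The labels name oligonucleotide sets 50, 100 and 190. HEK293T had all 3 sets, HepG2 had sets 50 and 100, and the other lines had set 50. What the numbers and the HepG2 labels ribo and no_ribo stand for is not given in the sources used here. Some titles of the HEK293T samples spell the line differently from the source label, which was followed.

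Per the submitters' processing notes, reads were handled with cutadapt, fastp, STAR, HISAT2 and StringTie on the builds hg38 and mm10, without versions. The authors deposited 1 interaction table per line or tissue. Each table lists a snoRNA region, a target region, the target's name and gene type, a count entry, a paired sequence and a free energy. The deposited count entry joins 2 whole numbers, read here as the chimeric reads of the 2 replicates. This reading was not stated in the sources used here. No column names a sample, so input and enriched libraries, oligonucleotide sets and the HepG2 labels could not be compared. An interaction entry pairs a read group of one replicate with one of the other, so that a read group can enter several interactions and sums of reads are not library depths. The deposited energy, in kcal/mol, is the authors' value for the paired stretch. The deposited TPM tables hold snoRNA and scaRNA genes and 2 value columns per line that carry no replicate number. TPM, as computed by the authors, keeps no depth, and the depth of the small RNA libraries is unknown. The number of columns per sample that were left unused was 0.

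An interaction is 1 entry of a table, and a pair is a distinct combination of snoRNA and target gene within a line. snoRNAs were classed by name as C/D (SNORD) or H/ACA (SNORA), and scaRNAs were left out of class comparisons. U3 stands for the SNORD3 copies, U8 for SNORD118, U13 for SNORD13 and U14 for SNORD14. Class shares were compared by two-sided Fisher's exact tests, with exact (Clopper-Pearson) 95% intervals for shares. Pairs are not independent replicates and each line is 1 table, so these intervals and p-values cover counting error alone. Overlap between lines was compared with 1000 shuffles that kept the number of targets of each snoRNA and of snoRNAs of each target, among snoRNAs of both lines. List members among SNORA73 mRNA targets were compared with mRNAs met only by other snoRNAs (Fisher's exact test, one-sided), over 9 lists and 5 lines. Pairing energies were computed with ViennaRNA 2.7.2 (RNAduplex) on the deposited arms and on the same arms with partners shuffled 10 times within a line; the permutation test swapped each interaction with its first shuffle in 100000 resamples. Abundance and number of targets were compared across snoRNAs by Spearman's rho and Pearson's r with 100000 permutations. TPM between lines was tested with limma on log2(TPM + 1), without a minimum, in 1 model over 6 libraries. For TPM, the scaRNA genes of the tables were counted among the snoRNAs. The snoRNAs at 0 in all 6 libraries, 68 of 407, have no fold and were left out, which departs from the design fixed before the data were examined. p-values were adjusted by the Benjamini-Hochberg method within each family of tests, at a threshold of 0.05. The duplicates are not described as separate cultures, so the limma p-values measure the spread between these samples, which may be technical.

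Human target regions were also placed on the RefSeq gene spans of the same build, which carry no strand and no exons. Exonic, intronic and UTR positions were therefore not assigned. No mouse annotation was used. The limma code was tested on simulated TPM values of A549 against PC3. With 40 of 339 snoRNAs changed 4-fold, 100% were recovered and 2 others were called. The simulated spread was a log2 SD of 0.105 for every snoRNA, and the changed ones had a TPM of at least 10. Some real snoRNAs varied more, such as SNORD14D with a standard error of 0.389, so this recovery may not carry over to them. The list test, in the form that counts each pair, made 1 call in 450 tests on HepG2 pairs with shuffled snoRNA labels. The main form, with mRNAs met only by other snoRNAs as background, was not checked in this way. The overlap test was checked on HEK293T and PC3 with 34 shared snoRNAs. Planting 365 to 377 shared pairs gave a ratio of observed to shuffled pairs of 1.27 to 1.28. With 20 thoroughly mixed tables in which no preference was left, the ratio was 0.990 to 1.03, with a mean of 1.01, and 5 of the 20 had p under 0.05. The p-values of the overlap test are therefore too small, and the ratios are to be read against this range. A first form of this check had mixed the tables too briefly and was replaced; mixing before and between shuffles was then lengthened to 100 trades per snoRNA and 100 trades.

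Named genes followed a rule fixed before the data were examined: SNORA73, 7SL, U3, U8, U13, U14 and mouse Htr2c; per line the 5 snoRNAs with most target genes; the 10 snoRNA-mRNA pairs in most lines and the 10 mRNAs met by most snoRNAs; per line the 5 SNORA73 mRNA targets with most reads; the 5 snoRNAs of highest TPM per line and the 5 largest TPM differences each way among those with a TPM of at least 10; and the 5 mouse targets with most reads per cluster. Lists of secreted, matrix, membrane, endoplasmic reticulum (ER), ribosomal, translation, mitochondrial, histone and cytosolic genes and of non-coding RNAs were fixed at the same time, as were neuronal, glial, vascular and proposed-target lists for mouse. Alternatives covered the support of interactions, the unit counted, host genes, merged copies, overlap of regions, background sets, pseudocounts, TPM minimums, scaling and left-out replicates. Software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, R 4.3.3 and limma 3.58.1.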

Results

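Small nucleolar RNAs guide the modification and cleavage of ribosomal RNA, and the series asked which other RNAs they meet in cells. Interactions from snoKARR-seq were tabulated for 5 human cell lines and for mouse brain, and snoRNA levels were measured by small RNA-seq in PC3, A549 and MDA-MB-231, with 2 libraries per line. The human tables held 41395 interactions of 106 snoRNAs with 7438 named target genes, which made 13106 distinct snoRNA-target pairs. HepG2 had 15878 interactions, MDA-MB-231 8257, PC3 7851, HEK293T 5373 and A549 4036. Every interaction had at least 2 reads in each replicate, and the median over both replicates was between 8 reads in HEK293T and 24 in A549. Over single interactions, Spearman's rho between the replicates lay between 0.119 in MDA-MB-231 and 0.439 in HEK293T. For reads summed per pair it lay between 0.552 in HepG2 and 0.796 in HEK293T, across pairs, which are not independent. Both sums of a pair grow with its number of interactions, so these higher values do not measure agreement of the replicates alone.

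U3, the C/D snoRNA needed for early cleavages of the pre-ribosomal RNA, took most of every table. Its copies made 66.0% of the pairs in MDA-MB-231, 68.8% in HepG2, 69.1% in A549, 69.2% in HEK293T and 77.1% in PC3. SNORD3A, on chromosome 17 from 19188016 to 19188232 (hg38), met the most target genes in each line, from 649 in A549 to 3239 in HepG2, and SNORD3C was next in each. The copies are nearly identical, so the division of reads among them is uncertain. SNORA73A and SNORA73B, the H/ACA family also known as U17 that acts in 18S rRNA processing, were among the 5 snoRNAs with most targets in all 5 lines. Merged, the SNORA73 family met 599 genes in HepG2, 380 in MDA-MB-231, 259 in PC3, 219 in HEK293T and 120 in A549. U8, which acts in the processing of 5.8S and 28S rRNA, met 79 genes in HEK293T, 77 in HepG2, 58 in MDA-MB-231 and 32 in PC3, and was not listed in A549, where its TPM was 10900. U13 met 44 genes in HepG2, 11 in A549, 8 in HEK293T and 6 in MDA-MB-231, and U14 met 36 in HepG2, 8 in HEK293T and 1 in A549; neither was listed in the remaining lines. The fixed list of snoRNAs that act in pre-rRNA processing made 83.3% to 91.2% of the interactions.

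The first comparison asked whether C/D and H/ACA snoRNAs contributed alike in each line. C/D snoRNAs made 79.2% of the pairs in MDA-MB-231 (exact 95% interval 77.8 to 80.4), below the 85.2% of HepG2, 84.8% of HEK293T, 86.1% of PC3 and 85.9% of A549. The 4 comparisons with MDA-MB-231 passed Fisher's exact test, the largest adjusted p being 4.09e-09. None of the other 6 did, with adjusted p of 0.265 or more. With interactions counted, however, 8 line pairs differed. With only snoRNAs in all 5 tables, a setting tried after the data had been seen, 7 did. Without U3 the C/D share was 38.6% in MDA-MB-231 and 39.5% in PC3, against 50.7% to 54.4% elsewhere, and PC3 then differed from HepG2, HEK293T and A549 (largest adjusted p = 3.58e-06, Fisher's exact test) but not from MDA-MB-231 (adjusted p = 0.717). HepG2 and HEK293T were enriched with more oligonucleotide sets than the other lines, which leaves their C/D shares less comparable with the rest. Shares in all lines, MDA-MB-231 included, also depend on which snoRNAs were listed, and only 16 of 106 were in all 5 tables. SNORA65, for example, was listed in MDA-MB-231 but not in A549, where its TPM was 1584. With the common snoRNAs alone, the C/D share was 84.5% in MDA-MB-231 and 86.8% to 90.3% elsewhere.

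With U3 among the C/D snoRNAs, H/ACA snoRNAs met mRNAs less often, and small nuclear and other non-coding RNAs more often, than C/D snoRNAs did in all 5 lines, but without U3 these differences were lost or turned around. In MDA-MB-231 mRNAs made 36.6% of H/ACA pairs and 50.2% of C/D pairs, and in PC3 36.6% and 49.3%. The difference was -11.7 percentage points in HEK293T, -9.68 in A549 and -4.30 in HepG2. Spliceosomal small nuclear RNAs made 24.5% of H/ACA pairs and 15.9% of C/D pairs in HEK293T, and the difference in the other lines lay between 2.58 points in HepG2 and 7.60 points in A549. Other non-coding RNAs, which include 7SL, 7SK and MALAT1, were higher for H/ACA by 4.04 points in HepG2 to 12.5 points in PC3. By name this class also held mitochondrial tRNA genes and, in HepG2, ENSG00000261012 and ENSG00000280390. Of the latter 2, 803 interactions of 33 snoRNAs and 215 of 17 lay in the span of the APOB gene. All 15 tests passed, the largest adjusted p being 0.0103 for mRNA in HepG2 (Fisher's exact test). U3 made most C/D pairs, and without it, a setting tried after these results were known, none of the 15 differences passed in the same direction. The mRNA share was then higher for H/ACA by 1.27 points in HepG2, 6.46 in HEK293T, 4.89 in PC3 and 3.29 in A549 and lower in MDA-MB-231 (-2.31), with adjusted p of 0.0861 or more (Fisher's exact test). The small nuclear RNA share was lower for H/ACA by -4.06 points in HepG2, -11.2 in HEK293T and -9.00 in PC3 (largest adjusted p = 0.0132, Fisher's exact test), with -3.42 in MDA-MB-231 and 5.40 in A549 not past the threshold. The difference in other non-coding RNA lay between -8.50 points in A549 and 1.5 in HepG2 (adjusted p of 0.166 or more). Without U3 and SNORA73 no difference passed, the smallest adjusted p being 0.185. The contrast above thus depended on U3. With U3 included, some of the HepG2 calls also ended in other settings: the mRNA difference was -3.12 points (adjusted p = 0.181, Fisher's exact test) among interactions with more reads than the median, and that of other non-coding RNA was 1.63 points with interactions counted (adjusted p = 0.169) and 1.07 points with targets placed by RefSeq span (adjusted p = 0.407). Among interactions with more reads than the median, the small nuclear RNA difference was 2.24 points in HepG2, 3.71 in PC3 and 6.25 in A549, no longer past the threshold, and 8.02 in HEK293T and 5.51 in MDA-MB-231, past it. Other settings enlarged differences: by RefSeq span that of mRNA was -27.3 points in PC3, -22.0 in MDA-MB-231 and -17.6 in HEK293T and that of other non-coding RNA 21.2 in PC3, and with interactions counted that of small nuclear RNA was 12.2 in A549 and 4.97 in HepG2 and that of other non-coding RNA 14.7 in MDA-MB-231. No target was typed as ribosomal RNA in any table. By RefSeq span, tried after the data had been seen, 41 pairs in PC3 to 63 in HEK293T lay on rRNA genes. These pairs include mitochondrial rRNA, on which 527 (16S) and 364 (12S) interactions lay over all lines. Pairs on mitochondrial and on other rRNA genes were not separated. Their share was higher for H/ACA than for C/D by 0.846 points in HepG2, 2.16 in HEK293T, 2.48 in PC3 and 1.32 in MDA-MB-231 (largest adjusted p = 0.0274, Fisher's exact test), and by 1.46 in A549 (adjusted p = 0.318), with U3 included and not tested without it. Between 19.9% of interactions in HepG2 and 27.8% in A549 lay outside the RefSeq span of the gene that named them, and a further 10.7% to 20.5% carried a name without a RefSeq span.

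**Figure D1:**
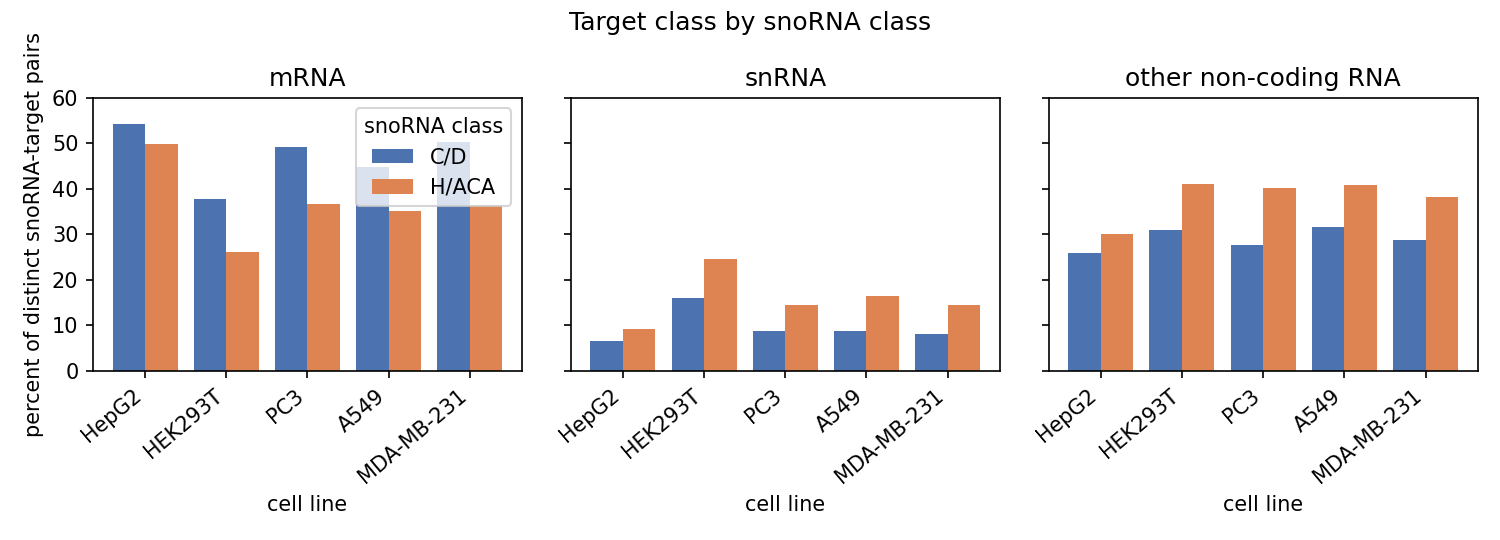
Percent of distinct snoRNA-target pairs (vertical axis) whose target was an mRNA, a small nuclear RNA or another non-coding RNA, per cell line (horizontal axis), for C/D snoRNAs, U3 included, and H/ACA snoRNAs. Bars stand for 1 table per line; the mRNA bar of H/ACA was the lower in every line, for example 36.6% against 50.2% in MDA-MB-231.

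Among fixed groups of non-coding targets, 7SL, the RNA of the signal recognition particle that brings secretory mRNAs to the ER, took 1.01% of interactions in HepG2 and 3.57% in A549, with values between them in the other lines. Small nuclear RNAs took 5.23% in HepG2 and 12.8% in HEK293T. The nuclear MALAT1 transcript had 659 interactions in MDA-MB-231, 356 in HepG2, 324 in A549, 269 in PC3 and 55 in HEK293T, and its group of nuclear long non-coding RNAs took 8.73% of interactions in MDA-MB-231 against 1.10% in HEK293T. The abundant polymerase III and ribonucleoprotein RNAs took 2.05% in HepG2 and 6.81% in A549. Among their members RMRP, the RNA of RNase MRP, had between 37 and 68 interactions per line, RPPH1, the RNA of RNase P, between 43 and 59, and the 7SK gene RN7SK between 38 and 47.

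The same snoRNA met the same target in different lines more often than in shuffled tables. Any pair of lines shared 729 to 1330 pairs, which was 36.8% to 51.3% of the smaller set when only snoRNAs listed in both lines were counted. The ratio of observed to shuffled pairs lay between 1.18 for HEK293T with MDA-MB-231 and 1.25 for HepG2 with HEK293T, outside the range of 0.990 to 1.03 that the check without preference gave for HEK293T and PC3. With copies merged to families it lay between 1.08 and 1.18. Each of the 10 one-sided p-values was 0.001, the smallest that 1000 shuffles can give, but this test called 5 of 20 tables without preference. Of the 13106 pairs, 361 were found in all 5 lines and 9543, or 72.8%, in a single line. The 10 mRNA pairs of highest support in all 5 lines all belonged to SNORD3A or SNORD3C. They included MT-ND4 with SNORD3A (18736 reads), MT-ND6 (12506), MT-CO1 (10654), MT-CO2 (8428), MT-ND5 (7989) and MT-CO3 (6889), named after mitochondrial genes of respiratory chain subunits. The most frequent placement of the regions named MT-CO3 in that pair was the span of ATP6, and 50.9% of all mitochondrial interactions lay outside the gene that named them. SNORD3A with MTRNR2L8 had 29803 reads. SNORD3A with HJV had 9879, and the most frequent placement of its regions was a lysine tRNA gene.

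By the target names of the tables, the mRNAs met by most snoRNAs were IGF2R, a receptor for insulin-like growth factor 2, with 40 snoRNAs, MTRNR2L8 with 39, MT-CO1 with 35, SLC26A3, an intestinal anion exchanger, with 31, MT-ND4 and MT-ND6 with 30 each, MT-ND5 with 28, MT-CO3 with 27, LINGO1 with 24 and MT-ATP6 with 23. By RefSeq span the order differed, with COX1 (MT-CO1) met by 44 snoRNAs and APOB by 33, while 88.4% of the MTRNR2L8 regions lay in no RefSeq gene. Of the IGF2R interactions 93.5% started within 1 window of 200 bases on chromosome 6, between 160100721 and 160100812 (hg38), and those of LINGO1 all lay between 77618526 and 77618612 on chromosome 15. At these spots, and at the main spot of SLC26A3, the median target arm was 100% A. A contact specific to these 3 mRNAs is therefore not shown.

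The title of the series links snoRNAs with protein secretion, and SNORA73 was therefore compared with the other snoRNAs for genes of the secretory pathway. In HepG2, 10 of 319 SNORA73 mRNA targets were secreted plasma proteins, against 18 of 2228 mRNAs met only by other snoRNAs (odds ratio 3.97, adjusted p = 0.0152, Fisher's exact test, one-sided). They included SERPINA1, the alpha-1 antitrypsin gene (27 interactions), ALB, which encodes albumin (10), and FN1, which encodes fibronectin (10). Secreted matrix genes made 7 against 12 (odds ratio 4.14, adjusted p = 0.0447), and genes of the ER and translocon 8 against 22 (odds ratio 2.58, adjusted p = 0.152). Mitochondrial transcripts had odds ratios of 8.31 in HepG2, 6.48 in PC3, 14.3 in A549 and 23.9 in MDA-MB-231, all past the threshold, and 5.05 in HEK293T with an adjusted p of 0.127. The membrane, ribosomal, translation, histone and cytosolic lists passed in no line, and the secreted and matrix lists passed in HepG2 and in no other line, a difference that was not tested. With SNORA73A alone neither HepG2 list passed (odds ratios 3.33 for secreted plasma and 1.52 for matrix genes), and with SNORA73B alone both did (5.10 and 7.43), a difference between the copies that was not tested. The background favours genes met by many snoRNAs. Against targets of other H/ACA snoRNAs 0 of the 45 tests passed. There the matrix list in HepG2 and the mitochondrial list in MDA-MB-231 had no background member. That loss of calls thus does not by itself argue against a preference. Likewise 0 of the 45 tests passed with each pair counted, or in shuffles that kept the number of snoRNAs of each gene. Those shuffles gave a mean of 11.4 secreted plasma genes among the SNORA73 targets of HepG2, where 10 were seen (permutation p = 0.846), 3.89 matrix genes where 7 were seen (p = 0.047, adjusted p = 1.0), and 10.1 mitochondrial transcripts where 7 were seen. Mitochondrial transcripts were below the shuffled mean in the other lines too. There 5 were seen against 10.4 in PC3, 4 against 6.65 in HEK293T, 7 against 9.53 in A549 and 10 against 11.1 in MDA-MB-231. The direction of their odds ratios above was thus not kept in any line.

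By reads, the SNORA73 mRNA target of highest support in HepG2 was MCM7, which encodes a subunit of the replicative helicase, with 1930 reads. Between 100098598 and 100098636 on chromosome 7 (hg38), the arm gctgggcctcgtgtctgcg of SNORA73 was listed as paired with TGCAGACACGGGGCTCCAGA, with a deposited energy of -36.5 kcal/mol. The tight junction gene CLDN23 had 720 reads in HepG2, SERPINA1 544, the linker histone gene H1-4 484 and CNRIP1 382. MCM7 and H1-4 were also among the 5 targets of highest support in HEK293T, with 86 and 72 reads. In PC3 the first was MTRNR2L8 with 1929 reads, followed by PSMA3, HJV, NUFIP1 and NCOA7, for each of which the most frequent placement was a tRNA gene. MTRNR2L8 was also first in HEK293T with 208 reads, in A549 with 552 and in MDA-MB-231 with 1645. In these lines and in PC3 its regions lay most often in no RefSeq gene, so a contact with an mRNA is not shown there. For regions named HJV in HEK293T, NFIB in A549 and VAC14, ZBED9 and ILF2 in MDA-MB-231, the most frequent placement was a tRNA gene.

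SNORA73 reads fell on 7SL more often than those of all other snoRNAs together in every line. The odds ratio was 2.46 in PC3, 2.27 in MDA-MB-231, 1.69 in A549, 1.15 in HEK293T and 1.12 in HepG2, with a largest adjusted p of 0.00028 over reads, which are not independent molecules. These values depended on single replicates: without replicate 1 the odds ratio was 0.985 in HepG2, 1.44 in PC3 and 1.53 in MDA-MB-231, and without replicate 2 it was 0.839 in HEK293T, 3.48 in PC3 and 2.93 in MDA-MB-231. With all names starting RN7SL it was 1.80 in HepG2. Counting interactions, a choice made after the data had been seen, 9.57% of those of SNORA73 were on 7SL in PC3 against 2.39% of the others, 9.45% against 2.95% in A549, 4.77% against 2.53% in HEK293T, 3.71% against 1.68% in MDA-MB-231 and 2.34% against 0.886% in HepG2, with adjusted p of 0.00516 or less (Fisher's exact test). The comparison group was mostly U3, of whose interactions only 0.505% in HepG2 and 1.52% in A549 lay on 7SL. Against C/D snoRNAs other than U3, the odds ratio was below 1 in every line, at 0.480 in HEK293T, 0.575 in PC3, 0.687 in HepG2, 0.864 in MDA-MB-231 and 0.931 in A549, with adjusted p of 0.00673 in HEK293T and PC3 and 0.157 or more in the others. Against other H/ACA snoRNAs it was 0.460 in HEK293T, 0.462 in PC3 and 0.382 in MDA-MB-231 (largest adjusted p = 0.0124), 1.55 in A549 (adjusted p = 0.253) and 11.3 in HepG2 (adjusted p = 0.00156), where 1 of 474 interactions of the other H/ACA snoRNAs was on 7SL. By share on 7SL, SNORA73 ranked 7 of 13 families with at least 20 interactions in A549, 10 of 24 in HepG2, 11 of 17 in PC3, 13 of 16 in HEK293T and 14 of 25 in MDA-MB-231. Of 96 SNORA73 interactions on RN7SL1, 29.2% centred on bases 201 to 250 of the gene and 26.0% on bases 51 to 100, where 42.0% and 12.0% of the 100 U3 interactions did.

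The deposited arms were paired more stably than shuffled partners. The median RNAduplex energy was -9.40 kcal/mol in HepG2, -10.7 in HEK293T, -9.70 in PC3, -9.50 in A549 and -9.60 in MDA-MB-231, and that of shuffled partners between -2.80 and -2.30. The permutation p was 1e-05 in each line, the smallest that 100000 resamples can give. Against dinucleotide-shuffled target arms the difference in medians shrank from -7.1 to -3.1 kcal/mol in HepG2 and from -7.9 to -3.9 in HEK293T, with -3.2 to -3.3 in the other lines. The tables list stretches already chosen for pairing, so the comparison does not bear on specificity. By the authors' deposited energies, H/ACA interactions had lower medians than C/D ones in each line, for example -15.1 against -11.9 kcal/mol in HEK293T, a difference that was not tested. The C/D medians include U3, and the classes were not compared without it. They also include deposited energies of 0, whose share was higher for C/D in each line, for example 16.8% against 7.84% in PC3.

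Among snoRNAs with a listed interaction, more abundant ones met more genes. Across these snoRNAs, which are not independent replicates, the rho of TPM with the number of target genes was 0.573 in MDA-MB-231 (57 snoRNAs, permutation p = 1e-05), 0.523 in A549 (49, p = 5e-05) and 0.382 in PC3 (49, p = 0.0071). Pearson's r was 0.584, 0.690 and 0.317, with permutation p of 1e-05, 1e-05 and 0.029. The adjusted p of rho was 3e-05, 7.5e-05 and 0.0071 in the same order. In PC3, leaving out the 2 snoRNAs farthest from the median TPM gave an r of 0.216 with a permutation p of 0.14, so that r there depended on them, and with total reads in place of targets r was 0.270 (permutation p = 0.059). In A549, leaving out U3 copies and SNORA73 lowered rho to 0.318 (permutation p = 0.037) and r to 0.397 (permutation p = 0.0081). With all measured snoRNA and scaRNA genes, those without a listed interaction counted at 0 targets, rho was 0.494 in MDA-MB-231, 0.433 in A549 and 0.460 in PC3 (permutation p = 0.0001 in each), though a 0 can also mean that a snoRNA was not enriched. With only those listed in at least 1 human table it was 0.554, 0.265 and 0.522 (largest permutation p = 0.0099). Among the 20 snoRNAs of highest TPM, 5 in MDA-MB-231, 6 in PC3 and 8 in A549 had no listed interaction.

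**Figure D2:**
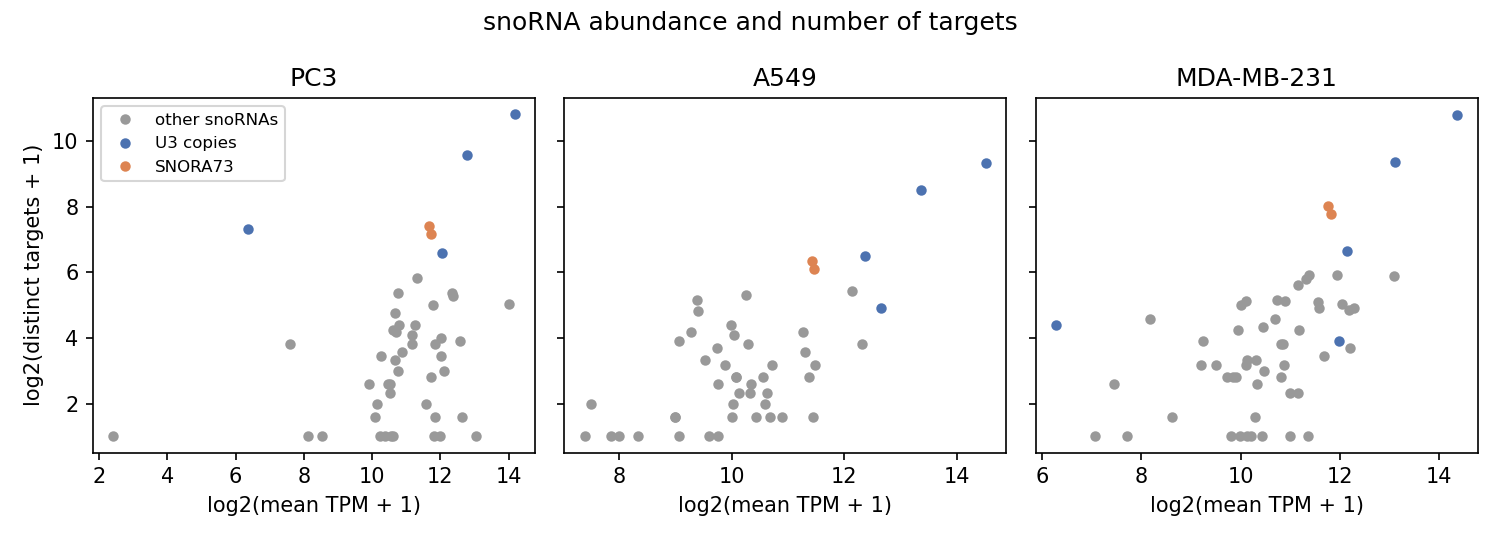
Number of distinct target genes per snoRNA, as log2(targets + 1), against log2(mean TPM + 1) in PC3, A549 and MDA-MB-231; each point is 1 snoRNA and TPM is the mean of 2 libraries. SNORD3A, SNORD3C and SNORA73 lie to the upper right. The U3 copy SNORD3B-1 lies to the left in PC3 (81.0 TPM, 158 targets) and in MDA-MB-231 (76.7 TPM, 20 targets). The rho was 0.382 in PC3, 0.523 in A549 and 0.573 in MDA-MB-231.

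SNORD3A had the highest TPM in all 3 lines, at 18530 ± 659 in PC3, 23552 ± 2765 in A549 and 21179 ± 8.96 in MDA-MB-231 (mean ± SD, n = 2), and SNORD118, SNORD3C and SNORD43 were among the first 5 in each. Of 339 snoRNA and scaRNA genes tested with limma, 48 were higher and 149 lower in A549 than in PC3. In MDA-MB-231, 37 were higher and 154 lower than in PC3, and 76 higher and 72 lower than in A549. With 1 library left out, the higher counts ranged from 23 to 35, 20 to 38 and 45 to 74 in that order. Rescaling TPM over snoRNAs shifted all log2 changes by 0.42, 0.28 and -0.14 and changed the counts to 86 and 98, 74 and 110, and 59 and 97. SNORD104 was lower in MDA-MB-231 than in PC3, at 1115 ± 6.44 against 5247 ± 569 TPM (n = 2; log2 change -2.23, limma adjusted p = 0.000318), and than in A549 by -2.01. U13 was lower in MDA-MB-231 than in PC3 by -2.0 and than in A549 by -1.57, and U8 was lower by -0.92 than in PC3. SNORD44, SNORD47 and SNORD75, which lie within 3 kb of one another on chromosome 1, were lower in A549 than in PC3 by -1.77, -1.88 and -1.55, and higher in MDA-MB-231 than in A549 by 1.13 for SNORD44 and 1.24 for SNORD75. SNORA80B was higher in A549 than in PC3 by 2.08, and SNORA65 higher in MDA-MB-231 than in A549 by 1.42. These kept their direction with rescaled TPM. Neither SNORA73 copy passed in any comparison, SNORA73A being at 2810 ± 197 TPM in A549, 3401 ± 430 in PC3 and 3614 ± 103 in MDA-MB-231 (n = 2), and the sign of its A549 against PC3 difference turned from -0.27 to 0.15 with rescaled TPM. Of the 16 measured members of the list of pre-rRNA processing snoRNAs, 5 were higher and 5 lower in A549 than in PC3, and as many adjusted over the list alone, against 6 and 2 with rescaled TPM. For MDA-MB-231 against PC3 the counts were 1 and 3, adjusted over the list alone 1 and 3, and 4 and 2 with rescaled TPM. For MDA-MB-231 against A549 they were 2 and 3, adjusted over the list alone 1 and 2, and 2 and 4 with rescaled TPM.

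In mouse brain the table covered Snord115 and Snord116, imprinted C/D clusters expressed in neurons. After removal of 2 repeated entries it held 63 interactions, 31 of Snord115 with 19 target genes and 32 of Snord116 with 16, and 8 genes were met by both clusters. Small nuclear RNA genes made 7 of the Snord115 and 5 of the Snord116 targets, and protein-coding genes 6 and 2. Snord115 had most reads on Rn7sk, the mouse 7SK gene (48 reads, chromosome 9, 78175304 to 78175448, mm10), then on Gm44066 (33), Dnah7b (25), Gm26444 (24) and Gm26244 (23). Snord116 had most on Gm26444 (48), Gm26244 (25), Gm44066 (24), Iqcg (24) and AC157822.2 (23). Htr2c, the serotonin receptor gene named as a Snord115 target, had 0 entries, and no member of the neuronal, glial, vascular or proposed-target lists was listed for either cluster, so the lists could not be compared between the clusters. Protein-coding targets outside these fixed lists, such as Cntnap5b (4 interactions) and Sorcs2 (1) of Snord115, were not classed by cell type. The median was 8 reads over both replicates, so rarer contacts were not detectable at this depth.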

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

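All tests in this part were chosen only after the tables had been seen; for the comparisons of SNORA73 with other groups, the deciding bounds were written before those results were known.

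The smaller share of mRNA among H/ACA pairs differed in size between the 5 lines (Woolf's chi-square test, p = 0.000961), being smallest in HepG2 at -4.30 points. The larger share of other non-coding RNA also differed between the lines (chi-square p = 0.0356), and that of small nuclear RNA did not pass (p = 0.378). These values include U3, without which the mRNA difference lay between -2.31 and 6.46 points and passed in no line, and the difference between lines was not tested without it. HepG2 and HEK293T had more oligonucleotide sets than the other lines, so a difference that involves HepG2 or HEK293T is also one between sets. The other lines carried the label 50, but whether it stands for the same oligonucleotides in each line is not given.

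The excess of SNORA73 interactions on 7SL over all other snoRNAs differed between the 5 lines (Woolf's chi-square test, p = 0.0156), with a pooled odds ratio of 2.99. It may reflect U3, which makes most of the comparison group and is seldom listed on 7SL, since against C/D snoRNAs without U3 the odds ratio was at or below 1 in 5 of the 5 lines. The bound set for a property of all H/ACA snoRNAs was met too. Against the other H/ACA snoRNAs the odds ratio was at or below 1 in 3 of the 5 lines. Such a property would, however, also put SNORA73 above C/D snoRNAs without U3, which was seen in no line. SNORA73 had far more listed interactions than those C/D families, for example 627 in PC3 where SNORD10, the largest of them, had 75. Shares on 7SL were not compared at equal numbers of interactions. This comparison therefore cannot decide whether such a property is the source of the excess. In HepG2 the odds ratio against the other H/ACA snoRNAs was 11.3, with 1 interaction of theirs on 7SL. A preference of SNORA73 over them there stays open. No biological explanation was tested.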

How the results depend on the processing

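Among the settings below, RefSeq placement, U3 or U3 and SNORA73 left out, snoRNAs common to all tables, each pair counted, shuffled pairs, 7SL by interactions or against other groups, the settings without the 2 snoRNAs farthest from the median TPM or without energies of 0, and snoRNAs without interactions counted at 0 targets were tried only after the data had been seen. The rho of abundance with targets kept its direction and its side of the threshold in the 27 alternatives run, though the A549 rho fell from 0.523 to 0.318 without U3 and SNORA73 and 0.265 with snoRNAs of any table. The p-values of overlap and pairing energy lay at the smallest that resampling allows and settle little. The median overlap ratio of 1.2 went to 1.12 with merged copies (lowest 1.08), 1.41 without U3 and 1.42 with targets matched by the stricter overlap of regions, and was above 1 in all 9 alternatives. The energy difference was negative in all 20, falling from -7.1 to -3.1 kcal/mol in HepG2 with dinucleotide-shuffled arms. The number of line pairs that differed in C/D share rose from 4 to 8 with interactions counted and to 7 with only snoRNAs in all 5 tables, and the cause was not tested. The target class differences held in 0 lines without U3, and in 0 without U3 and SNORA73. Without U3, H/ACA minus C/D was 1.27, 6.46, 4.89 and 3.29 points for mRNA in HepG2, HEK293T, PC3 and A549, -4.06, -11.2, -9.00 and -3.42 for small nuclear RNA in HepG2, HEK293T, PC3 and MDA-MB-231, and -0.564 and -8.50 for other non-coding RNA in HEK293T and A549. Without SNORA73 as well it was 4.50 for mRNA in A549, -3.05 and -4.59 for small nuclear RNA in HEK293T and PC3 and -8.86 for other non-coding RNA in A549. These differences thus depended on U3. Among interactions with more reads than the line's median, the small nuclear RNA share stayed higher for H/ACA in all 5 lines but past the threshold in 2, and the HepG2 mRNA difference of -3.12 points was not past it; nor was that of other non-coding RNA in HepG2 with interactions counted (1.63) or RefSeq placement (1.07). The cause was not tested.

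Calls for the gene lists fell from 6 to 3 with more reads than the median, where the HepG2 odds ratios were 2.60 for secreted plasma and 4.33 for mitochondrial genes, and the PC3 one 3.44, while mitochondrial genes still passed with 7.18 in A549 and 8.83 in MDA-MB-231. They fell to 1 with SNORA73A alone, with 3.33, 1.52 (matrix) and 2.08 in HepG2, 5.87 in PC3 and 10.0 in A549, and 46.3 in MDA-MB-231, which passed; SNORA73B alone gave 7 calls, with 5.10, 7.43 and 14.9 in HepG2. They fell to 0 against targets of other H/ACA snoRNAs, with 2.78 for secreted plasma, and 1.93, 0.428 and 1.11 for mitochondrial genes in HepG2, PC3 and A549. Matrix in HepG2 and mitochondrial in MDA-MB-231 gave no odds ratio there, with no background member. They fell to 0 with each pair counted, with 1.29 and 2.41 for secreted plasma and matrix, and 0.749, 1.10, 1.22 and 1.42 for mitochondrial genes in HepG2, PC3, A549 and MDA-MB-231, and to 0 in shuffled pairs. With RefSeq placement the matrix list had 3.29 (not past the threshold) and mitochondrial genes in HEK293T 10.3 (past it), and mitochondrial genes rose to 67.5 in A549 and 46.8 in MDA-MB-231. The cause was not tested.

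For 7SL, single replicates gave odds ratios of 0.985 to 1.18 in HepG2 and 0.839 to 1.30 in HEK293T, 1.44 to 3.48 in PC3 and 1.53 to 2.93 in MDA-MB-231, and the cause was not tested. All names starting RN7SL gave 1.80 in HepG2. Against other H/ACA snoRNAs they were 0.460, 0.462, 1.55 and 0.382 in HEK293T, PC3, A549 and MDA-MB-231, and against C/D snoRNAs without U3 0.687, 0.480, 0.575, 0.931 and 0.864 from HepG2 to MDA-MB-231, by the change of comparison group.

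With TPM rescaled over snoRNAs, limma called 86 higher and 98 lower in A549 than PC3, and 74 higher in MDA-MB-231 than PC3. With a library left out, the lone library being assumed to vary like the others, the higher calls ranged from 23 to 35 for A549 over PC3, 20 to 38 for MDA-MB-231 over PC3, and 45 to 74 for MDA-MB-231 over A549. In mouse, interactions with more reads than the median had 9 Snord115 and 8 Snord116 targets, fewer interactions being counted. No paired analysis was possible because the interaction tables have no sample columns and the TPM columns carry no replicate number, so the replicate block was not run. FPKM and exonic targets were not run either. Interactions with 2 reads in a replicate limit what rarer contacts can show.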

Other observations

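Tests of naming, hub spots, the U3 stretch and the shuffled lists were chosen only after the results had been seen, as were the imprinted clusters and APOB; the bound for pairs counted was written before that result.

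In HepG2 the APOB gene, which encodes the main protein of low-density lipoprotein, held 1049 interactions of 33 snoRNAs by RefSeq span, with 52665 reads (chromosome 2, 21001429 to 21044073, hg38). Only 31 of them were named APOB, while 803 were named ENSG00000261012 and 215 ENSG00000280390.

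Some imprinted C/D clusters differed between some of the lines. All 7 tested SNORD113 copies and 16 of 22 SNORD114 copies of the chromosome 14 cluster were lower in A549 than in PC3 and in MDA-MB-231 than in PC3 (limma), as many as with TPM rescaled over snoRNAs, with SNORD114 TPM sums of 560.0 in PC3, 14.6 in A549 and 3.68 in MDA-MB-231. Of 25 SNORD116 copies, 22 were lower in MDA-MB-231 than in PC3 and 22 than in A549, likewise with rescaled TPM. Their TPM sums were 589.1, 596.4 and 19.0 in PC3, A549 and MDA-MB-231. For A549 against PC3, 4 SNORD116 copies were higher and 3 lower (7 and 1 with rescaled TPM). SNORD107, SNORD109, SNORD115 and SNORD64 had 0 calls in that comparison. The copies of a cluster resemble one another, so reads of single copies are uncertain.

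Of 5626 interactions with mitochondrial names, 50.9% lay outside the gene that named them, and 527 named MT-TL1 lay on the 16S rRNA gene RNR2 and 364 named MT-TV on the 12S rRNA gene RNR1. Naming after the nearest gene start may account for this, since 99.9% carried the name of the gene with the nearest 5 prime end. An annotation of another build is argued against by the snoRNA arms, of which 0.0121% lay outside their named gene. Target names are thus uncertain where a region lies outside the named gene.

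The secreted plasma list in HepG2 could reflect genes met by many snoRNAs. With each pair counted its odds ratio was 1.29, above the bound of 1.2 set for that explanation, so these cannot be told apart by that test. The shuffled pairs, at 11.4 genes for 10 seen, weigh toward widely met genes. A role of SNORA73 in secretion was not tested.

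Of 8 spots, each with target regions starting within 1 window of 200 bases and met by 10 or more snoRNA families, 3 (37.5%) lay on a tRNA or small nuclear RNA gene, those named HJV, WDR74 and LTA4H. In the others the median share of A in the target arms was 60%, against 20% elsewhere. Per spot, the median arm was 100% A at IGF2R, SLC26A3, LINGO1 and RASGEF1B, and 26.7% at MTRNR2L8.

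The hypothesis that U3 stands out on a stretch upstream of 18S rRNA gene copies on chromosome 21 was tested. U3 made 413 of 450 interactions there, or 91.8%, against 75.2% elsewhere, a difference of 16.6 points (Fisher's exact test, p = 1.96e-19). The interactions were pooled over the 5 lines and over nearly identical U3 copies. They are not independent, so the p-value covers counting error alone. In HepG2 U3 made 80.8% against 76.1%, and in MDA-MB-231 95.2% against 70.2%.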
